A study of Mus musculus with 8 samples.

How the data were processed

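RNA was extracted with an RNeasy kit from cells cultured in DMEM/F12 with 5% adult bovine serum, and libraries were made with the KAPA mRNA HyperPrep kit, per the labels' protocols. Per the submitters' processing notes, the authors aligned single-end reads with STAR 2.6.1a to the GRCm38 (mm10) genome with an Ensembl annotation, counted reads per gene with featureCounts in its reverse-stranded mode, and tested differences with DESeq2. The version of featureCounts and the treatment of reads that map to several genes are not recorded. The files the authors deposited hold 1 column of raw read counts per library, as whole numbers, for the same 53379 Ensembl genes in each of the 8 files. No row without a gene was present. Total counts ranged from 12442730 to 19149916 per library, so 3 counts correspond to 0.157 to 0.241 CPM in a single library; the floor used for zeros is lower, 3 counts over both libraries of a line together.

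Gene symbols, coordinates, exon lengths and GC content came from the GENCODE M21 annotation of the same build, which gave a symbol to 53274 gene IDs and none to 105. The list symbols Ctgf and Cyr61 appear there as Ccn2 and Ccn1. For the 1 list symbol with 2 gene IDs, Aldoa, the ID with more counts was used, a choice made after the data were seen. Libraries were grouped by cell line, 2 per line, and the fluorescent protein of the reporter was not analysed here.

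Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by line with its defaults, which left 15890. TMM factors, a quasi-likelihood negative binomial fit of all 8 libraries with 1 coefficient per line, and quasi-likelihood F tests followed, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05, two-sided. All lines shared 1 fit because 2 libraries per line leave few residual degrees of freedom (4, with a median prior of 9.35). The common dispersion was 0.0318, a biological coefficient of variation of 0.178. The contrasts were pB3 against pB2, 687g against Epcam hi, the difference between those contrasts, Epcam hi against pB2, and 687g against pB3. Genes called the same way in both pairs were counted beside the number that independent lists of the same sizes would share, with one-sided Fisher's exact tests. CPM values use the TMM-scaled totals.

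Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 20 lists of a contrast. Camera compares a list with the other genes. It was also run with the correlation estimated from the data, and fry was run to ask whether the genes of a list move on balance. The 20 lists hold 367 genes, of which 295 were tested. They cover epithelial adhesion, epithelial regulators, EMT transcription factors, mesenchymal genes, fibrillar matrix, basement membrane, luminal and basal mammary genes, MHC class I, interferon-stimulated genes, immunosuppressive factors, chemokines and cytokines, the TGF-beta response, the cell cycle, hypoxia and glycolysis, cholesterol synthesis, and markers of leukocytes, endothelium, fibroblasts and adipocytes. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where an addition is named.

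The rule named a panel of 9 genes, the 4 called genes with the largest fold in each direction for the pairs of the same mouse model (3 for the other pairs), and the 2 called members with the largest fold of each list that is not a marker list. For the difference between the pairs it named the 5 called genes with the largest difference each way among genes called in both pairs with a mean of at least 10 CPM in the higher line of both pairs. Folds for this ranking were ratios of mean CPM with the lower mean raised to that of 3 counts over the line, for genes of at least 10 CPM in the higher line; some genes that the rule selects are not reported here, and members named beyond the rule were chosen after their values were seen. Where a line had 0 counts the fold is given as a lower bound against that floor. Where it had 1 to 3 counts, the fold is the ratio of count sums per total with an exact 95% Poisson counting interval. Fitted log2 fold changes of such genes depend on the prior count, and intervals and floors cover counting error only.

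The scripts were tested on simulated data for 15122 genes, with the mean of each gene over all 8 libraries and the sizes of those libraries. Changes were put only into pB3, in 100 genes per fold size and a list, fewer than differed in the real data. Genes were drawn independently of each other. In that test 48% of genes changed 2-fold and 72% of genes changed 4-fold were called in the right direction, 0.0604% of unchanged genes were called, and genes raised 4-fold had a median fitted log2 change of 2.04. A list shifted 1.5-fold had a camera adjusted p of 3.56e-07, and 2.5% of 200 unchanged lists had p under 0.05. As the simulated genes were independent, this does not show how camera behaves for lists of correlated genes.

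The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter on low counts, a stricter filter (at least 1 CPM in both libraries of a line and 50 counts in total), a minimum fold change of 2, a replicate block, a fit of only the libraries compared, and each library left out in turn. Total counts without scaling factors were added after the data were seen. For lists, the alternatives were the estimated correlation, fry, the block, RLE factors and each library left out. No library was left out of the main analysis.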

Results

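Messenger RNA was sequenced from 4 mouse mammary carcinoma cell lines on the C57BL/6 background, each with 2 libraries of cells grown as a monolayer. pB2 and pB3 were derived from tumours of MMTV-PyMT mice, whose mammary epithelium expresses the polyoma virus middle T oncogene. Epcam hi and 687g were derived from MMTV-PyMT-Snail-IRES-YFP mice, which the labels call a reporter model and whose name joins Snail, a transcription factor, to a yellow fluorescent protein. The series is described as a set of models of the epithelial-mesenchymal transition (EMT), and the question put to each pair of lines from the same mouse model was how far its members differ in epithelial, mesenchymal and immune-related genes. The labels do not say which line is epithelial or mesenchymal, nor whether the replicates are separate cultures, so the p-values measure only the spread between these samples.

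Total counts were 12442730 and 16895237 in the pB2 libraries, 15631003 and 15916987 in pB3, 13701156 and 18515857 in Epcam hi, and 19149916 and 16094250 in 687g. Between 21087 and 22935 genes had at least 1 count in a library, and mitochondrial genes took 0.375% to 1.90% of the counts. The first principal component carried 53.4% of the variance between libraries and set pB2 apart from the other lines, and the second, with 26.5%, parted Epcam hi from 687g. Replicates correlated across genes with r of 0.992 in pB2, 0.993 in pB3, 0.976 in Epcam hi and 0.986 in 687g. The Epcam hi libraries stood furthest apart, with 13.4% of genes over 2-fold apart against 2.96% in pB2, 3.22% in pB3 and 6.32% in 687g. In what follows, a value after ± is the SD of 2 libraries for CPM (counts scaled to a common library total) and the standard error of the fit for log2 fold changes.

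Vim, the mesenchymal intermediate filament vimentin, stood at 13.8 and 14.1 CPM in the pB2 libraries and at 26.9 ± 7.88 in Epcam hi, against 2371 ± 86.6 in pB3 and 2862 ± 745 in 687g (SD, n = 2). Cdh1, which encodes E-cadherin, reached 155 ± 16.5 CPM in pB2, 51.4 ± 0.604 in pB3, 488 ± 43.9 in Epcam hi and 1.32 ± 0.819 in 687g. Epcam, an epithelial adhesion molecule, followed the same order, with 566 ± 18.4, 271 ± 9.60, 1473 ± 89.9 and 3.77 ± 0.111 CPM. The EMT transcription factor Zeb1 was near the floor in pB2 (0.101 ± 0.0672 CPM) and low in Epcam hi (0.696 ± 0.487), and stood at 27.5 ± 0.629 CPM in pB3 and 45.5 ± 5.74 in 687g. Snai1, which encodes Snail, was at 16.3 ± 2.27 CPM in pB2, 9.58 ± 1.66 in pB3, 4.53 ± 1.15 in Epcam hi and 20.3 ± 7.83 in 687g, so it was lowest in a line of the Snail-IRES-YFP model. Fn1 (fibronectin) had 214 ± 62.3, 2259 ± 0.859, 2874 ± 112 and 9005 ± 5359 CPM in pB2, pB3, Epcam hi and 687g.

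Of 3 genes for secreted or surface factors that act on immune cells, Nt5e, whose enzyme makes extracellular adenosine, had 18.8 ± 1.99 CPM in pB2, 226 ± 8.71 in pB3, 295 ± 27.0 in Epcam hi and 1157 ± 267 in 687g. Csf1, a growth factor for macrophages, had 25.9 ± 7.10, 59.6 ± 2.45, 12.8 ± 4.04 and 83.0 ± 35.2 CPM in the same order. Spp1, which encodes osteopontin, had 366 ± 7.92, 5256 ± 194, 374 ± 36.7 and 18184 ± 677 CPM. In the GRCm38 annotation these 9 genes lie as follows: Cdh1 on chromosome 8 from 106603351 to 106670246, Epcam on 17 from 87635979 to 87651129, and Vim on 2 from 13573927 to 13582826. Fn1 lies on chromosome 1 from 71585520 to 71653200, Zeb1 on 18 from 5591860 to 5775467, and Snai1 on 2 from 167538195 to 167542814. Nt5e lies on chromosome 9 from 88327197 to 88372092, Csf1 on 3 from 107741048 to 107760469, and Spp1 on 5 from 104435118 to 104441050.

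**Figure D1:**
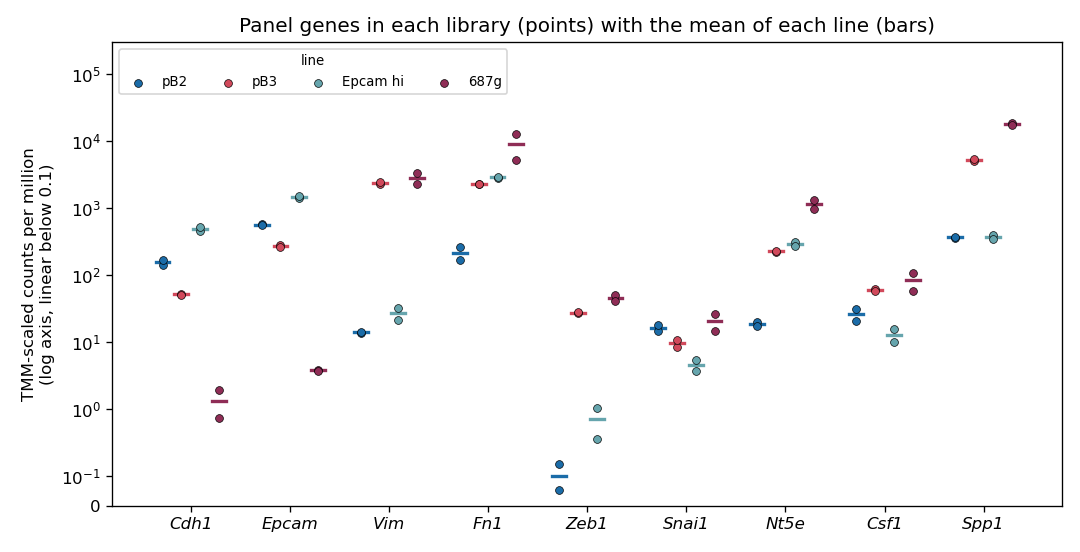
Expression of 9 genes in the 4 lines, in CPM on a log axis; points are libraries, bars the mean of 2 libraries. Vim and Zeb1 were high in pB3 and 687g, and Cdh1 was lowest in 687g, at 1.32 CPM.

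The pB3 line was compared with pB2 to ask how lines of the MMTV-PyMT model differ. Vim was higher in pB3 by 7.41 ± 0.30 on the log2 scale (adjusted p = 4.13e-10, n = 2 libraries per line), Zeb1 by 297-fold (counting interval 101 to 1444) from 3 counts in pB2, and Fn1 by 3.40 ± 0.35 (adjusted p = 2.79e-06). Cdh1 and Epcam were lower in pB3, with log2 fold changes of -1.60 ± 0.23 and -1.06 ± 0.17 (adjusted p = 5.45e-05 and 1.31e-04). Nt5e rose by 3.59 ± 0.22 and Spp1 by 3.84 ± 0.20 (adjusted p = 1.34e-08 and 2.94e-09). Csf1 rose by 1.20 ± 0.29 (adjusted p = 0.00421), a call that ended without pB2 replicate 1 (0.94, adjusted p = 0.0709). Snai1 was lower in pB3 at -0.77 ± 0.29 (adjusted p = 0.0442), and that call ended without any single library of the pair, with adjusted p of 0.0717 and 0.219 without pB2 replicates 1 and 2 and of 0.262 and 0.0627 without pB3 replicates 1 and 2, and with limma-voom (0.0577). Zeb1 moved from 8.09 on the log2 scale to 8.82 and 7.46 without pB2 replicates 1 and 2.

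The largest rises in pB3 were those of Mmp3, a stromelysin that degrades matrix, from 6 counts in pB2 to 386 CPM, and of the kallikrein-related protease Klk6, by 2298-fold (counting interval 636 to 18983) from 2 counts. Sema7a, a membrane-anchored semaphorin, rose by 1596-fold (counting interval 546 to 7741) and the peptidase Cpq by 1094-fold (counting interval 374 to 5307), each from 3 counts in pB2. Without pB2 replicate 2, the fitted log2 fold change of Mmp3 moved from 10.97 ± 0.52 to 12.19, and that of Sema7a moved from 10.52 to 11.24 and 9.88 without pB2 replicates 1 and 2. Igfbp5, an insulin-like growth factor binding protein, fell from 5414 ± 1212 CPM in pB2 to 3.79 ± 1.87 in pB3, a log2 fold change of -10.48 ± 0.54 that reached -11.10 without pB3 replicate 1. Each with 3 counts in pB3, the neurotrophin receptor gene Ntrk2 was lower by 1236-fold (counting interval 423 to 5997), Hp (haptoglobin) by 1102-fold (counting interval 377 to 5348), and Sntb1 (a syntrophin) by 1051-fold (counting interval 359 to 5098).

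Of 24 epithelial adhesion and polarity genes, 20 fell in pB3, 3 rose and 1 was not called, with the same counts adjusted over the list alone. Their median log2 fold change was -1.41 (camera, adjusted p = 1.02e-04; adjusted p = 0.379 with an estimated correlation). The tight junction gene Tjp3 was lower by 625-fold (counting interval 112 to 24717) with 1 count in pB3, whereas the desmosomal plaque gene Pkp1 rose by 6.33 ± 0.43 and Cldn4, of tight junctions, by 2.90 ± 0.27. Without pB3 replicates 1 and 2, the fitted log2 fold change of Tjp3 moved from -8.98 to -11.38 and -8.10. Of 18 epithelial regulators of transcription and splicing, 14 fell, 3 rose and 1 was not called, also adjusted over the list alone, with a median of -3.51 (-3.48 with genes near zero counts held at their bound). The camera test gave adjusted p = 1.02e-04, and adjusted p = 0.379 with an estimated correlation. The transcription factor genes Tfap2c and Ehf fell from 173 and 75.9 CPM in pB2 to 5 and 4 counts in pB3. Their fitted log2 fold changes rested on single pB3 libraries: Tfap2c moved from -9.97 ± 0.34 to -11.22 and -9.29, and Ehf from -9.08 ± 0.47 to -13.26 and -8.10, without replicates 1 and 2.

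Among 16 EMT transcription factors, 11 rose in pB3, 4 fell and 1 was not called, both over all genes and adjusted over the list alone (median 0.91; camera, adjusted p = 0.0286; adjusted p = 0.53 with an estimated correlation). Prrx1, a mesenchymal homeobox gene, rose from 4 counts in pB2 to 77.7 ± 0.291 CPM, with a log2 fold change of 9.21 ± 0.35 (9.88 without pB2 replicate 2), and the chromatin protein gene Hmga2 by 8.80 ± 0.28. Of 18 mesenchymal cytoskeleton and adhesion genes, 12 rose, 4 fell and 2 were not called, and 13 rose and 4 fell adjusted over the list alone (median 2.27; camera, adjusted p = 0.00326; adjusted p = 0.417 with an estimated correlation). The receptor tyrosine kinase gene Axl rose by 9.20 ± 0.35, and the ligand gene Wnt5a by 745-fold (counting interval 206 to 6154) from 2 counts in pB2. The fitted log2 fold change of Wnt5a moved from 9.36 to 12.56 and 8.20 without pB2 replicates 1 and 2. Hmga2 and Axl were also high in Epcam hi, a line low in Vim, at 449 ± 84.8 and 361 ± 53.6 CPM. Prrx1 and Wnt5a were low there, at 0.442 and 0.837 CPM. Fibroblast markers moved with these genes: of the 5 of 12 that were tested, Gsn (3.71 ± 0.24), Fbln1 (3.45 ± 0.33) and Smoc2 (2.59 ± 0.57) rose in pB3 and Pdgfra fell (-1.84 ± 0.22), with the same counts adjusted over the list alone (median 2.59, 2.67 with genes near zero counts at their bound; camera, adjusted p = 0.297).

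Of 15 fibrillar matrix genes, 8 rose, 5 fell and 2 were not called, also adjusted over the list alone (median 2.08, 2.09 with genes near zero counts at their bound; camera, adjusted p = 0.297). Tnc, which encodes tenascin C, rose by 8.28 ± 0.30, and Fstl1, a secreted follistatin-like protein, fell by 7.64 ± 0.33 on the log2 scale, to 22 counts in pB3 (-8.53 without pB3 replicate 1). Of 15 basement membrane genes, 10 rose, 2 fell and 3 were not called, with the same counts adjusted over the list alone (median 2.29; camera, adjusted p = 0.00702; adjusted p = 0.433 with an estimated correlation). The type IV collagen genes Col4a1 and Col4a2 rose by 8.86 ± 0.39 and 8.54 ± 0.35. Tnc, Col4a1 and Col4a2 were high in Epcam hi as well, at 735 ± 51.9, 297 ± 23.7 and 168 ± 5.24 CPM. Fstl1 was low there, at 0.860 CPM. Of the 15 basement membrane genes, 9 were higher and 4 lower in Epcam hi than in pB2 (camera, adjusted p = 0.0573). The low level in pB2 was thus shared by neither pB3 nor Epcam hi.

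Luminal mammary genes were divided: of 19, 8 rose, 9 fell and 2 were not called, also adjusted over the list alone. Their median was 0.14 (0.15 with genes near zero counts at their bound), their mean -2.23, and the direction of the test was down (camera, adjusted p = 0.544). Lcn2 (lipocalin) fell from 1426 ± 59.0 CPM to 1.39 ± 0.13 and the whey acidic protein family gene Wfdc18 from 657 ± 43.9 to 0.765 ± 0.44. The luminal keratin genes Krt8 and Krt18 rose by 2.27 ± 0.20 and 3.22 ± 0.19. Without pB3 replicate 1, the fitted log2 fold change of Wfdc18 moved from -9.74 ± 0.33 to -10.48. Of 11 basal and myoepithelial genes, 4 rose, 5 fell and 2 were not called, and 5 rose and 5 fell adjusted over the list alone (median 0.07, mean -1.37, direction down; camera, adjusted p = 0.607). Trp63, a basal transcription factor gene with 0 counts in pB3, was at least 350.0-fold lower against a floor of 3 counts over the line, and the basal keratin gene Krt14 fell by 3.80 ± 0.20. The endothelial marker Erg, the 1 of 10 such markers tested, fell with these genes, from 6.13 ± 1.76 CPM in pB2 to 0 in pB3, and also adjusted over the list alone. As a list its median was -9.62 (-5.95 at its bound), with camera adjusted p = 0.0803, and 0.0377 and 0.0455 without pB2 replicates 1 and 2.

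Interferon-stimulated genes were lower in pB3: of 22, 12 fell, 0 rose and 10 were not called, and 13 fell and 2 rose adjusted over the list alone. Their median was -1.30 (camera, adjusted p = 0.00622; adjusted p = 0.53 with an estimated correlation). The receptor transporter Rtp4 fell by 2.42 ± 0.34. Of 18 genes of antigen presentation by MHC class I, 7 rose, 4 fell and 7 were not called, and 7 rose and 5 fell adjusted over the list alone. The median of that list was -0.26 and its mean -0.18, while the test pointed up (camera, adjusted p = 0.787). B2m, the light chain of class I molecules, rose by 2.56 ± 0.18, and the immunoproteasome subunit gene Psmb8 fell by 3.28 ± 0.53 on the log2 scale (-3.90 without pB3 replicate 2).

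Of 18 immunosuppressive factors, 12 rose in pB3, 5 fell and 1 was not called, and 13 rose and 5 fell adjusted over the list alone; the list holds genes that work on these lines has studied (Nt5e, Csf1, Spp1), so it is not independent evidence. Its median was 1.47 (camera, adjusted p = 0.0117; adjusted p = 0.379 with an estimated correlation). The prostaglandin synthase gene Ptgs2 rose by 7.89 ± 0.23, and Tgfb2, a ligand of the TGF-beta family, fell by 6.02 ± 0.47 on the log2 scale. Of 17 chemokines and cytokines, 8 rose, 5 fell and 4 were not called, also adjusted over the list alone (median 1.48, 1.34 with genes near zero counts at their bound; camera, adjusted p = 0.297). Tslp, an epithelial cytokine of type 2 immunity, rose from 13 counts in pB2 to 376 ± 20.7 CPM, and the granulocyte-macrophage factor Csf2 from 5 counts to 106 ± 4.38. Without pB2 replicates 1 and 2, the log2 fold change of Tslp moved from 9.83 ± 0.39 to 10.73 and 9.12, and that of Csf2 moved from 9.36 ± 0.96 to 10.33 without replicate 2. Of 17 TGF-beta response genes, 10 rose, 3 fell and 4 were not called, with the same counts adjusted over the list alone (median 1.27; camera, adjusted p = 0.0117; adjusted p = 0.53 with an estimated correlation). Inhba, an activin subunit gene, rose by 7.34 ± 0.28, and Id2, an inhibitor of differentiation factors, fell by 3.16 ± 0.21 on the log2 scale. In Epcam hi, Ptgs2, Csf2 and Inhba were high as well, at 1264 ± 66.7, 121 ± 1.96 and 332 ± 89.5 CPM. Tslp was far lower there than in pB3, at 13.5 ± 2.43 CPM. Tgfb2 and Id2 were lower in Epcam hi than in pB2, as in pB3.

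Of 23 cell cycle genes, 7 fell, 0 rose and 16 were not called, and 6 fell and 0 rose adjusted over the list alone (median -0.23; camera, adjusted p = 0.118). Tyms (thymidylate synthase) and Birc5 (survivin) fell by 2.11 ± 0.29 and by 1.51 ± 0.21 on the log2 scale. Both lie in chromosome stretches where most genes were lower in pB3 than in pB2, and lower in Epcam hi than in pB2 as well. Tyms lies on chromosome 5 (median of the stretch in pB3 against pB2 -1.43) and Birc5 on chromosome 11 (median -0.94). Among 17 hypoxia and glycolysis genes, 7 rose, 4 fell and 6 were not called, also adjusted over the list alone (median 0.14; camera, adjusted p = 0.483), with Car9 (carbonic anhydrase) and Pdk1 (a pyruvate dehydrogenase kinase) at -2.39 ± 0.20 and -1.90 ± 0.19. Cholesterol synthesis genes gave 3 that rose, 6 that fell and 8 not called of 17, also adjusted over the list alone (median -0.32; camera, adjusted p = 0.51), with the sterol demethylase gene Cyp51 at -1.31 ± 0.18 and Msmo1 at 1.07 ± 0.19. Cyp51 lies in the same stretch of chromosome 5 as Tyms and fell by about the median of that stretch. Neither of the 2 leukocyte markers tested of 13 was called, over all genes or adjusted over the list alone (median 0.15, 0.19 at its bound; camera, adjusted p = 0.857). Of the 2 adipocyte markers tested of 8, Fabp4 fell and Plin4 was not called, also adjusted over the list alone (median -1.16, -1.21 at its bound; camera, adjusted p = 0.524).

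Across the 15890 genes tested with edgeR, 7116 differed between pB3 and pB2, with 3427 higher and 3689 lower in pB3. With total counts in place of the scaling factors, an alternative added after the data were seen, 2766 were higher and 4591 lower, and the median log2 fold change of all genes shifted by -0.19. Camera called 8 of the 20 lists, 5 up and 3 down. With an estimated correlation camera called 0, with 2 at an unadjusted p under 0.05, and fry, which asks only whether the genes of a list move on balance, called 18.

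687g was compared with Epcam hi to ask the same question in the Snail-IRES-YFP reporter model. Cdh1 was lower in 687g by 8.49 ± 0.33 on the log2 scale and Epcam by 8.60 ± 0.24, falling to 1.32 and 3.77 CPM (n = 2 libraries per line). Vim rose by 6.73 ± 0.29 (adjusted p = 7.71e-10), Zeb1 by 5.95 ± 0.34 (adjusted p = 1.08e-08) and Snai1 by 2.17 ± 0.30 (adjusted p = 7.02e-05). Spp1 rose by 5.60 ± 0.22, Csf1 by 2.71 ± 0.31 and Nt5e by 1.97 ± 0.20 (adjusted p = 3.18e-10, 1.07e-05 and 3.16e-06). Fn1 rose by 1.65 ± 0.33 (adjusted p = 0.0013), a value that fell to 0.88 (adjusted p = 0.0121) without 687g replicate 1. Leaving out 687g replicate 1 also moved Cdh1 from -8.49 to -9.33, and leaving out Epcam hi replicate 2 moved Zeb1 to 7.06.

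The largest rises in 687g were those of Notum, a secreted inhibitor of Wnt ligands, by 1600.3-fold (counting interval 547 to 7763) from 3 counts in Epcam hi, and of Tnfaip8l3, a lipid transfer protein, by 1363-fold (counting interval 377 to 11264) from 2 counts. Smoc2, a secreted matricellular protein, rose from 22 counts in Epcam hi to 746 ± 58.1 CPM and the potassium channel family gene Kctd12b from 4 counts to 103 ± 20.7. Plekhs1 and Bspry fell from 113 ± 71.9 and 75.8 ± 4.37 CPM in Epcam hi to 4 counts each, and the claudin gene Cldn7 fell by 9.24 ± 0.26 on the log2 scale. Single libraries moved several of these fitted log2 fold changes: Notum from 10.49 to 11.17 and Smoc2 from 10.07 ± 0.46 to 10.90 without Epcam hi replicate 1, and Kctd12b from 9.63 ± 0.40 to 10.44 without Epcam hi replicate 2. Plekhs1 moved from -9.76 ± 0.66 to -8.90 without Epcam hi replicate 1 and to -13.77 and -8.87 without 687g replicates 1 and 2.

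Of the 24 epithelial adhesion and polarity genes, 22 fell in 687g, 1 rose and 1 was not called, also adjusted over the list alone. Their median was -7.90 (-7.98 with genes near zero counts at their bound; camera, adjusted p = 6.46e-18; adjusted p = 0.0782 with an estimated correlation). Crb3, a gene of apical polarity with 0 counts in 687g, was at least 605-fold lower against a floor of 3 counts over the line, and Cldn4 fell by 9.09 ± 0.37. Pkp1 was the member that rose, by 2.99 ± 0.31. Of 18 epithelial regulators, 9 fell, 3 rose and 6 were not called, and 10 fell and 3 rose adjusted over the list alone. Their median was -2.21, and -1.03 with genes near zero counts at their bound (camera, adjusted p = 0.00467; adjusted p = 0.351 with an estimated correlation). The splicing regulator gene Esrp1 fell by 8.75 ± 0.33 on the log2 scale and the transcription factor gene Grhl2 fell by 7.95 ± 0.39. Without 687g replicate 1 these became -9.55 for Esrp1 and -7.24 for Grhl2, and Grhl2 was at -8.95 without 687g replicate 2.

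EMT transcription factors rose in 687g: of 16, 10 rose, 0 fell and 6 were not called, also adjusted over the list alone (median 1.41; camera, adjusted p = 3.68e-05; adjusted p = 0.351 with an estimated correlation). Prrx1 rose by 8.44 ± 0.30 and Twist2 by 7.78 ± 0.45, from 15 and 4 counts in Epcam hi. Without Epcam hi replicate 2, Prrx1 was at 9.21 and Twist2 at 11.82, and Twist2 was at 6.98 without replicate 1. Of 18 mesenchymal cytoskeleton and adhesion genes, 12 rose, 3 fell and 3 were not called, also adjusted over the list alone (median 1.54; camera, adjusted p = 3.12e-04; adjusted p = 0.351 with an estimated correlation). The calcium-binding protein gene S100a4 rose from 6.16 ± 1.74 to 782 ± 80.1 CPM (SD), and the growth factor receptor gene Pdgfrb rose by 359.5-fold (counting interval 64.1 to 14240.0) from 1 count. The fitted log2 fold change of Pdgfrb moved from 8.13 to 10.47 and 7.19 without Epcam hi replicates 1 and 2. Tpm2, Cd44 and Actn1 fell, with log2 fold changes of -6.37 ± 0.40, -1.89 ± 0.19 and -0.65 ± 0.23.

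Some fibroblast and adipocyte markers rose with the mesenchymal and matrix genes in 687g. Only 5 of 12 fibroblast and 2 of 8 adipocyte markers passed the low-count filter, so these results do not describe the whole lists. Of 5 fibroblast markers tested, 4 rose, 0 fell and 1 was not called, and 4 rose and 1 fell adjusted over the list alone, with Smoc2 at 746 CPM in 687g. The median of that list was 2.16 (1.68 with genes near zero counts at their bound; camera, adjusted p = 0.015; adjusted p = 0.358 with an estimated correlation). Both adipocyte markers tested rose, also adjusted over the list alone, with Fabp4 at 13.0 ± 4.72 CPM and Plin4 at 2.70 ± 0.682 CPM in 687g (median 6.72, 4.97 at the bound; camera, adjusted p = 0.015; adjusted p = 0.351 with an estimated correlation). Of 15 fibrillar matrix genes, 9 rose, 4 fell and 2 were not called, also adjusted over the list alone (median 2.06; camera, adjusted p = 0.032; adjusted p = 0.453 with an estimated correlation). Fstl1 rose by 8.20 ± 0.32 and the type VI collagen gene Col6a1 by 231-fold (counting interval 78.9 to 1125) from 3 counts. Without Epcam hi replicate 1 and without 687g replicate 1, the fitted log2 fold change of Col6a1 moved from 7.68 to 8.37 and 6.95. Basement membrane genes were divided, with 5 that rose, 4 that fell and 6 not called of 15, also adjusted over the list alone (median 0.10, mean -0.20, direction down; camera, adjusted p = 0.896). The laminin gene Lama3 fell by 8.71 ± 0.34 on the log2 scale (-9.62 without 687g replicate 1), and Nid1 (nidogen) rose by 8.07 ± 0.50.

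Of 19 luminal genes, 4 rose, 6 fell and 9 were not called, also adjusted over the list alone (median -0.80, -0.08 with genes near zero counts at their bound; camera, adjusted p = 0.432). Ly6a, a surface antigen of progenitor cells, fell by 5.25 ± 0.22 and Cd24a rose by 2.58 ± 0.20. Krt8 and Krt18 were lower in 687g, with log2 fold changes of -1.06 ± 0.19 and -1.34 ± 0.18. Of 11 basal and myoepithelial genes, 5 fell, 0 rose and 6 were not called, also adjusted over the list alone (median -0.67, -0.48 at the bound; camera, adjusted p = 0.175). The integrin gene Itgb4 fell by 3.04 ± 0.29 and the transcription factor gene Sox9 by 1.49 ± 0.19 on the log2 scale.

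In 687g, 9 of 18 MHC class I genes fell, 4 rose and 5 were not called, also adjusted over the list alone. Their median was -0.51 (-0.53 at the bound), with camera adjusted p = 0.0809, and 0.0448 without Epcam hi replicate 2. The class I transactivator gene Nlrc5 fell by 5.00 ± 0.26 and H2-Q4 by 4.36 ± 0.34; H2-Q4 belongs to a family of closely related genes, so its counts are uncertain. Of 22 interferon-stimulated genes, 7 rose, 3 fell and 12 were not called, also adjusted over the list alone (median 0.38, 0.24 at the bound). The camera test gave adjusted p = 0.165, and 0.0171 without Epcam hi replicate 1. Usp18, a protease that removes the ubiquitin-like modifier ISG15, fell by 4.06 ± 0.36 on the log2 scale (-4.90 without 687g replicate 1), and the antiviral membrane protein gene Bst2 by 1.80 ± 0.26. Isg15 itself rose by 2.65 ± 0.35 and Rtp4 by 5.03 ± 0.57.

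Of the 18 immunosuppressive factors, 7 rose, 5 fell and 6 were not called, also adjusted over the list alone (median 0.44, 0.14 at the bound; camera, adjusted p = 0.408); as above, the list is not independent evidence. Spp1 and Csf1 led those that rose, and the checkpoint ligand gene Cd274 fell by 2.78 ± 0.55. Of 17 chemokines and cytokines, 5 rose, 6 fell and 6 were not called, and 6 rose and 7 fell adjusted over the list alone (median -0.54, -0.53 at the bound; camera, adjusted p = 0.996). The inflammatory cytokine gene Il6 rose from 9 counts in Epcam hi to 205 ± 81.1 CPM, a log2 fold change of 9.49 ± 0.47 (10.22 without Epcam hi replicate 1). Il1a fell from 44.6 ± 17.8 CPM in Epcam hi to 4 counts in 687g. TGF-beta response genes rose in 687g: of 17, 11 rose, 2 fell and 4 were not called, and 12 rose and 2 fell adjusted over the list alone (median 1.68; camera, adjusted p = 1.74e-04; adjusted p = 0.351 with an estimated correlation). Id1 rose by 8.06 ± 0.27 and Id2 by 4.68 ± 0.23.

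Cell cycle genes were lower in 687g: of 23, 11 fell, 2 rose and 10 were not called, also adjusted over the list alone (median -0.46; camera, adjusted p = 0.032; adjusted p = 0.351 with an estimated correlation). That list call ended without Epcam hi replicate 2 (adjusted p = 0.353), pB3 replicate 1 (0.0570) or pB3 replicate 2 (0.0563). The cyclin gene Ccne1 fell by 2.32 ± 0.20 and Tyms rose by 1.43 ± 0.29, or by 2.20 without Epcam hi replicate 2. Of 17 hypoxia and glycolysis genes, 6 rose, 4 fell and 7 were not called, and 6 rose and 5 fell adjusted over the list alone (median 0.17, 0.08 at the bound, mean -0.19, camera up with adjusted p = 0.799, fry down with adjusted p = 0.0397). Car9 fell by 6.39 ± 0.25 and the stress-induced gene Ndrg1 fell by 4.33 ± 0.28. Of 17 cholesterol synthesis genes, 2 rose, 3 fell and 12 were not called, also adjusted over the list alone (median 0.06, mean -0.08, direction down; camera, adjusted p = 0.976), with the sterol reductase gene Dhcr7 at -1.14 ± 0.19. The leukocyte markers Csf1r and Cd68 went opposite ways, also adjusted over the list alone, with log2 fold changes of 2.18 ± 0.80 and -4.16 ± 0.47 (median -0.99; camera, adjusted p = 0.726). Erg was not called, over all genes or adjusted over the list alone, at 0 CPM in Epcam hi and 0.0615 in 687g (camera, adjusted p = 0.482).

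Between 687g and Epcam hi, edgeR called 5789 of the 15890 genes, with 2927 higher and 2862 lower in 687g; with total counts in place of the scaling factors 2445 were higher and 3405 lower, and the median of all genes shifted by -0.12. Camera called 9 of the 20 lists, 6 up and 3 down; with an estimated correlation it called 0, with 1 at an unadjusted p under 0.05, and fry called 15. The larger spread of the Epcam hi libraries, with 13.4% of genes over 2-fold apart, bears on every value of this pair. All lines shared 1 estimate of spread, so the p-values here also drew on the tighter pB2 and pB3 libraries. A fit of only the 4 libraries compared called 4207 genes and kept 72.1% of the 5789 calls. The same kind of fit called 9354 genes for pB3 against pB2, where the shared fit called 7116. The shared fit thus gave more calls for this pair and fewer for pB3 against pB2.

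**Figure D2:**
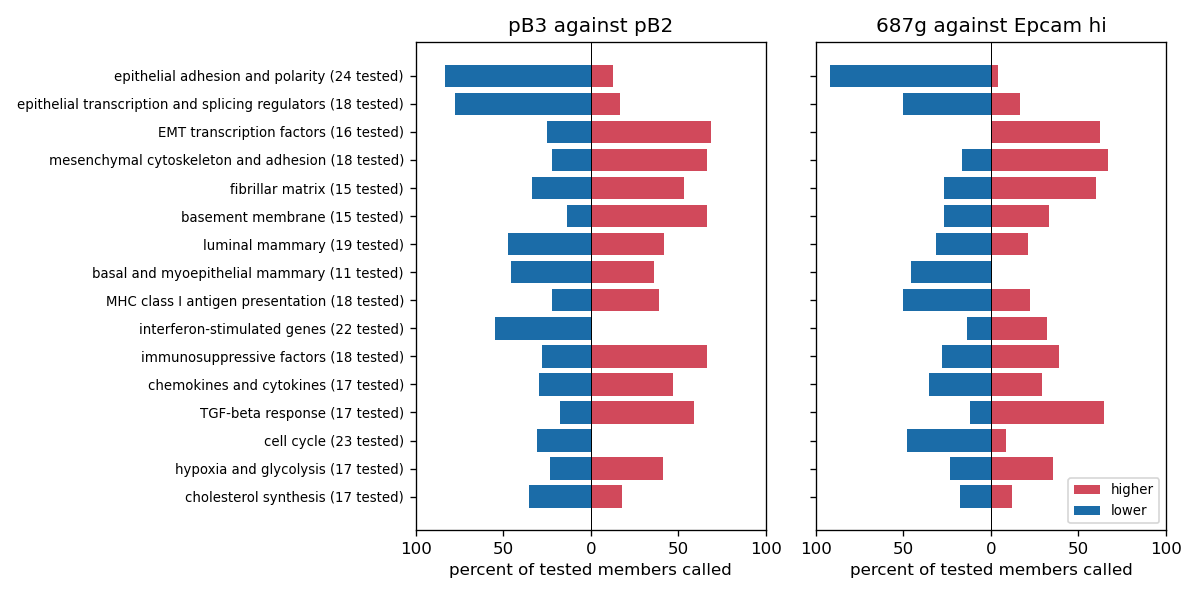
The percent of the tested genes of each list that were called higher or lower in pB3 against pB2 and in 687g against Epcam hi, at an adjusted p under 0.05. The marker lists of other cell types are not shown. In the epithelial adhesion list 20 of 24 genes were lower in pB3 and 22 of 24 in 687g.

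The pairs were then set against each other to ask which differences they share. In both, 1040 genes were higher in the Vim-rich line (pB3 and 687g), against 631.3 for independent lists of those sizes (Fisher's exact test, one-sided, p = 3.09e-84), and 859 were lower, against 664.4 (p = 8.87e-21). Another 777 genes were higher in pB3 and lower in 687g, against 617.2 (Fisher's exact test, one-sided, p = 2.53e-15), and 636 were lower in pB3 and higher in 687g, against 679.5 (p = 0.984). Genes called in both pairs thus numbered 3312, of which 1899 went the same way and 1413 opposite ways; genes are not independent replicates, and the pairs share the estimate of spread but no library. Independent lists would share 2592.4 genes over all directions and 1296.7 in opposite ones, so part of the excess did not depend on direction. The Fisher p-values therefore do not measure shared direction alone. Across genes, the log2 fold changes of the pairs correlated with Pearson's r of 0.0650 and Spearman's rho of 0.0619. As chosen examples, Zeb1, Vim, Prrx1 and S100a4 were higher and Cdh1, Epcam, Esrp1 and Grhl2 lower in both pB3 and 687g. Other epithelial and EMT genes did not follow these: Snai1, Cldn4, Krt8 and Krt18 went opposite ways in the pairs, and Pkp1 rose in both.

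**Figure D3:**
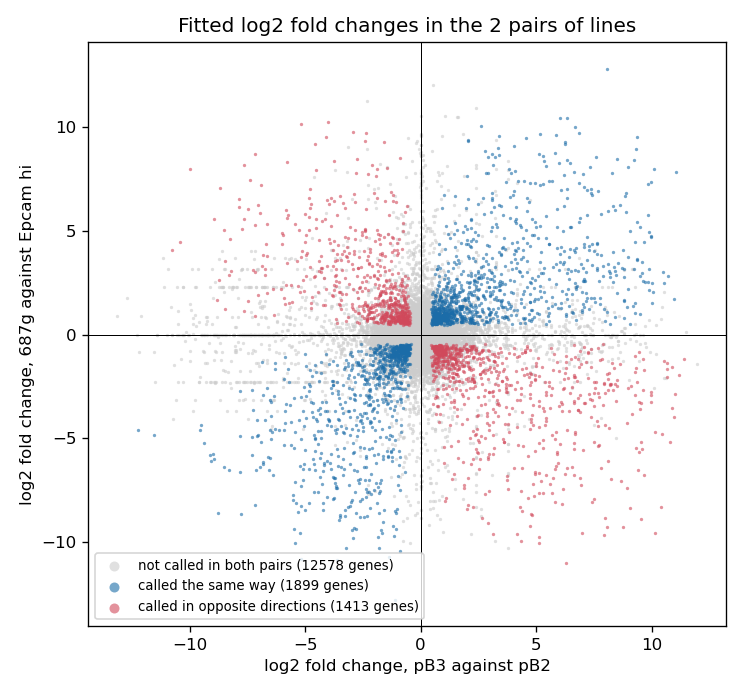
Log2 fold change of 687g against Epcam hi (vertical axis) over that of pB3 against pB2 (horizontal axis) for each tested gene, coloured by the calls in both pairs. The points spread over every combination of directions, with 1899 genes called the same way and 1413 opposite ways.

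The difference between the pairs was tested itself, as the log2 fold change of 687g against Epcam hi minus that of pB3 against pB2. Epithelial adhesion genes fell further in 687g: 21 of 24 had a lower value, 0 a higher one and 3 were not called, also adjusted over the list alone (median -5.36; camera, adjusted p = 6.64e-11; adjusted p = 0.193 with an estimated correlation). Cdh1 had a difference of -6.89 ± 0.38 (adjusted p = 6.84e-09) and Epcam of -7.54 ± 0.27 (adjusted p = 2.04e-10). Interferon-stimulated genes had a positive difference: 13 of 22 were higher, 2 lower and 7 not called, and 14 higher and 2 lower adjusted over the list alone. Their median was 1.59 (camera, adjusted p = 0.00861, and 0.837 with an estimated correlation). As a list they were not called in 687g against Epcam hi (camera, adjusted p = 0.165). They were lower than in pB2 in both pB3 and Epcam hi (camera, adjusted p = 0.00622 and 0.00229). Neither of those calls held with an estimated correlation. The difference thus lay mostly in their higher level in pB2. Vim did not pass this test, at -0.68 ± 0.33 (adjusted p = 0.128), while Fn1 (-1.75 ± 0.46), Zeb1 (-2.14 ± 0.78) and Nt5e (-1.62 ± 0.28) had lower values and Snai1 (2.94 ± 0.42), Csf1 (1.51 ± 0.42) and Spp1 (1.76 ± 0.25) higher ones.

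Among genes well expressed in both pairs, those with the largest positive difference were low in pB3 and Epcam hi. The matricellular genes Smoc1 and Fstl1 had differences of 15.89 ± 0.49 and 15.84 ± 0.46, with Smoc1 at 100.4, 0.696, 0.367 and 159.7 CPM in pB2, pB3, Epcam hi and 687g. Hey1, a target of Notch signalling, was at 15.75 ± 0.51 and the phosphatase gene Alpl at 14.82 ± 0.67. Eva1a had 0 counts in pB3, so its fitted difference of 14.88 ± 0.84 depends on the prior count. At the other end, Col8a1, a network-forming collagen, was at -15.12 ± 0.55, with 0.355, 247, 136 and 2.68 CPM in the same order. Dynap was at -15.50 ± 0.34 and the mast cell protease family gene Mcpt8 at -15.92 ± 0.60. The hedgehog ligand gene Dhh had 0 counts in pB2, so its fitted difference of -14.93 ± 0.67 also depends on the prior count.

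Single libraries moved several of these fitted differences by over 1.5 times, all of them genes with few counts in some line. Without pB3 replicate 1, Fstl1 was at 16.75 and Alpl at 14.11, and Alpl was at 16.51 without pB3 replicate 2. Without Epcam hi replicate 1, Hey1 was at 16.81, Eva1a at 15.67 and Alpl at 14.06, and without Epcam hi replicate 2, Hey1 was at 15.10 and Alpl at 17.97. Mcpt8 was at -19.63 and -14.68 without pB2 replicates 1 and 2, and at -16.52 without 687g replicate 2.

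Of the other lists, the difference between the pairs was closest to the threshold for basement membrane genes, with 4 higher, 9 lower and 2 not called of 15, also adjusted over the list alone. Camera gave them adjusted p = 0.0639, and 0.0444 without 687g replicate 1. Both adipocyte markers, Fabp4 and Plin4, had higher values, also adjusted over the list alone, with the same adjusted p of 0.0639 for the list, and 0.0429 without pB3 replicate 1. The endothelial marker Erg had a higher value, also adjusted over the list alone (camera, adjusted p = 0.153). Among epithelial regulators 5 were higher and 9 lower (camera, adjusted p = 0.756; median -2.02, mean 0.19), among EMT transcription factors 7 and 6 (0.636), among mesenchymal genes 6 and 9 (0.636), among fibrillar matrix genes 5 and 4 (0.756), and among luminal genes 7 and 7 (0.65), all also adjusted over the list alone. For basal genes 3 were higher and 5 lower, and 3 and 6 adjusted over the list alone (camera down, adjusted p = 0.756; median -0.62, mean 0.79, fry up with adjusted p = 0.0016).

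MHC class I genes counted 3 higher and 9 lower for the difference between the pairs, and 4 and 9 adjusted over the list alone (camera, adjusted p = 0.438). Immunosuppressive factors counted 6 and 7, and 6 and 8 adjusted over the list alone (0.636), in a list that is not independent evidence. Chemokines and cytokines counted 2 and 8, and 3 and 8 adjusted over the list alone (0.636), and TGF-beta response genes 6 and 5, and 8 and 5 adjusted over the list alone (0.65). Cell cycle genes counted 3 and 2 (0.721), hypoxia genes 5 and 6 (0.636), leukocyte markers 0 and 1 (0.739) and fibroblast markers 2 and 1 (0.636), all also adjusted over the list alone. Cholesterol genes counted 4 and 4, and 5 and 4 adjusted over the list alone (0.721). In all, 5994 genes passed the test of the difference, 2896 with a higher and 3098 with a lower value. Camera called 2 of the 20 lists, with an estimated correlation 0 (1 at an unadjusted p under 0.05), and fry 12.

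Lines of different mouse models were also compared, where the model of origin and the line cannot be told apart. Against pB2, Epcam hi had 1087 ± 145 CPM of Ly6a in place of 0.577 ± 0.0835, a log2 fold change of 10.84 ± 0.30 (n = 2 libraries per line). The interferon-inducible gene Ifi209 was higher by 3676-fold (counting interval 1017 to 30359) from 2 counts in pB2, and the phosphatase gene Ptpn22 by 1795-fold (counting interval 614 to 8708) from 3 counts; Ly6a and Ifi209 belong to families of related genes, so their counts are uncertain. The chemokine receptor gene Cxcr4 fell from 219 ± 37.5 CPM in pB2 to 4 counts in Epcam hi, Timp3, an inhibitor of metalloproteinases, from 728 ± 105 CPM to 16 counts, and the metalloreductase gene Steap4 from 173 ± 9.44 CPM to 4 counts. Without pB2 replicates 1 and 2, the fitted log2 fold change of Ifi209 moved from 11.71 to 10.97 and 14.78, and that of Ptpn22 from 10.73 to 9.97 and 14.34. In total 8172 genes differed, 4103 higher and 4069 lower in Epcam hi. Under total counts 3527 were higher and 4539 lower, and the median of all genes shifted by -0.11.

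Between 687g and pB3, the lines richest in Vim, 4093 genes differed, 2039 higher and 2054 lower in 687g, and 2474 and 2402 were called without pB3 replicates 1 and 2. Abcc3, an export transporter gene, rose from 5 counts in pB3 to 179 ± 24.8 CPM in 687g, the secreted factor gene Fam19a5 by 2763-fold (counting interval 496 to 109185) from 1 count, and Tnfaip8l3 by 1272-fold (counting interval 352 to 10510.1) from 2 counts. Tenm4, a teneurin gene, fell from 54.3 ± 2.08 CPM to 5 counts, Palmd by 1704-fold (counting interval 305 to 67352) with 1 count in 687g, and the zinc finger gene Zfp275 by 474-fold (counting interval 131 to 3919) with 2. Leaving out pB3 replicates 1 and 2 moved the fitted log2 fold change of Abcc3 from 10.01 ± 0.53 to 11.27 and 9.34, of Fam19a5 from 11.14 to 13.55 and 10.27, and of Tnfaip8l3 from 10.15 to 13.41 and 9.21. Leaving out 687g replicates 1 and 2 moved Palmd from -10.41 to -12.67 and -9.67, and Tenm4 from -8.41 ± 0.45 to -12.74 and -7.56.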

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

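The tests of endothelial RNA, fibroblast RNA and exchanged labels were chosen after the result was seen. The results below were singled out because the difference between the pairs, 687g against Epcam hi minus pB3 against pB2, passed its own test. That test called 5994 genes and 2 lists, with a median of -5.36 for epithelial adhesion and polarity genes and of 1.59 for interferon-stimulated genes. Of 90 genes that the rule selects for the pairs of the same mouse model and for the difference between them, 81 passed. Of these, 29 were called in opposite directions in the pairs and 23 in the same direction, and values are given for 77. Over all tested genes 37.7% passed. The higher share among the 90 follows in part from the rule, which picked some genes because they passed and most for a large fold. Fitted values of genes with few counts in a line depend on the prior count.

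Genes that fell in pB3 and rose in 687g had log2 differences of 15.89 for Smoc1, 15.84 for Fstl1, 15.75 for Hey1, 14.88 for Eva1a, 14.82 for Alpl, 14.26 for Tnfaip8l3, 9.50 for Id1, 7.84 for Id2 and 7.45 for Rtp4. In this group the remaining differences were 3.54 for Tyms, 3.41 for Cd24a, 2.94 for Snai1 and 2.50 for Pdk1. The fall of Snai1 in pB3 was near the threshold (edgeR, adjusted p = 0.0442) and was not called with limma-voom (adjusted p = 0.0577). Genes that fell in pB3, and in 687g fell less or were not called, had differences of 13.02 for Trp63, 11.61 for Igfbp5, 11.13 for Sntb1, 10.28 for Ntrk2, 10.16 for Wfdc18, 10.03 for Hp, 9.20 for Lcn2, 8.70 for Tfap2c and 6.18 for Tgfb2. The others of that kind had 1.40 for Cyp51, 1.34 for Krt14 and 1.11 for Birc5. Trp63, Sntb1, Ntrk2, Hp and Tgfb2 had 2 to 10 counts in Epcam hi and in 687g, so they could hardly fall between those lines. Igfbp5, Wfdc18, Lcn2 and Tfap2c were also far lower in both of those lines than in pB2. For these genes the difference mainly restates their high level in pB2. Genes that rose more in 687g, or rose there without a call in pB3, had differences of 8.87 for Notum, 7.99 for Nid1, 7.48 for Smoc2, 6.99 for Pdgfrb, 6.88 for Col6a1, 3.87 for Twist2, 1.76 for Spp1 and 1.51 for Csf1.

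Genes that rose in pB3 and fell in 687g had log2 differences of -3.95 for B2m, -6.11 for Ndrg1, -7.79 for Nlrc5, -8.35 for Ptgs2, -9.67 for Tnc, -11.65 for Csf2, -11.80 for Sema7a, -11.87 for Ly6a and -13.53 for Lama3. More genes with these directions had -13.86 for Klk6, -14.93 for Dhh, -15.12 for Col8a1, -15.50 for Dynap and -15.92 for Mcpt8. Genes that rose in both and rose more in pB3 had differences of -1.62 for Nt5e, -1.75 for Fn1, -2.14 for Zeb1, -2.61 for Cpq, -3.33 for Pkp1, -3.91 for Wnt5a, -7.28 for Tslp, -7.82 for Axl and -9.27 for Mmp3. Genes that rose in pB3 without a call in 687g had differences of -1.26 for Msmo1, -7.03 for Inhba, -8.48 for Hmga2, -8.86 for Col4a2 and -9.28 for Col4a1. Inhba, Hmga2, Col4a2 and Col4a1 were already high in Epcam hi, at 332, 449, 168 and 297 CPM. Genes that fell in 687g, and in pB3 fell less or were not called, had differences of -0.81 for Dhcr7, -1.45 for Bst2, -1.47 for Ccne1, -3.11 for Itgb4, -4.00 for Car9, -4.03 for H2-Q4, -4.18 for Grhl2, -4.36 for Usp18 and -5.48 for Esrp1. Besides these, the differences were -6.89 for Cdh1, -7.54 for Epcam, -7.92 for Plekhs1, -8.02 for Cldn7, -9.56 for Bspry, -11.05 for Il1a and -11.70 for Crb3.

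pB2 stood apart from the other lines on the first principal component, and 7116 genes differed between it and pB3. With every library thinned to the lowest total, 95.3% of those calls were kept in the same direction. This argues against uneven depth as the source of most of those calls. The principal component was not computed again on thinned libraries. Erg stood at 6.13 CPM in pB2 while the median of the 9 other endothelial markers was 0 CPM, with Pecam1 the highest at 0.413, and Pdgfra stood at 51.6 CPM while the median of the 11 other fibroblast markers was 0 CPM, with Gsn the highest at 12.4. These levels argue against endothelial or fibroblast RNA in the pB2 cultures. A difference between the tumours or lines themselves may account for the pattern, as a hypothesis, and stays untested because each state and mouse model has 1 line.

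Genes called in opposite directions in the pairs numbered 1413. With trends of GC content and transcript length entered as offsets, 96.3% of them were still called in opposite directions, which argues against such a bias. If labels had been exchanged within a pair, epithelial adhesion genes would go opposite ways; of the 23 called in both pairs, 21 (91.3%) went the same way. Regulation that differs between the lines may underlie the pattern, as a hypothesis. The mouse model, the tumour of origin and the line stay open and untested, since the design holds 1 pair per mouse model.

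The Epcam hi libraries had 13.4% of genes over 2-fold apart, against at most 6.32% in another line. That share was 13.8% with replicate 2 thinned to the total of replicate 1, 11.1% with the length and GC trend of the difference removed, and 13.7% with the implied RNA of each other line (0.160% to 0.385%) taken out. Each of these shares stayed above 6.32%, which argues against depth, such a trend or RNA of another line as the whole cause. Median log2 differences of replicate 2 from replicate 1 were -1.09 for the 2 leukocyte markers, -0.46 for interferon-stimulated genes and -0.36 for MHC class I genes, against 0.28 for epithelial regulators, 0.25 for hypoxia and glycolysis and for luminal genes, and 0.13 for cell cycle genes (15 of 23 higher). Mitochondrial genes took 0.375% and 1.09% of the counts; the cause stays open, and no biological explanation was tested, since the labels give no date or density.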

How the results depend on the processing

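Total counts without scaling factors are the alternative added after the data were seen. The 117 named gene results gave 1979 pairs of a result and an alternative. Of these pairs, 1972 kept their direction and side of the threshold, 7 lost the call and 0 turned round. Apart from the panel, the named genes were chosen for large folds or differences in the main fit. Most were therefore likely to keep their calls, and the count does not describe all called genes. The losses were those of Snai1 in pB3 against pB2 (6 alternatives, including a minimum fold change of 2) and of Csf1 in the same pair without pB2 replicate 1; over all their alternatives adjusted p ranged from 9.43e-04 to 0.262 for Snai1 and from 6.31e-07 to 0.0709 for Csf1. A library left out leaves its line with 1 library, which is then assumed to vary like the others. Genes changed between 687g and pB3 numbered 2402 to 4991 with 1 library left out, from 4093. The ranges were 5032 to 8094 for pB3 against pB2, 4990 to 7150 for 687g against Epcam hi, 4633 to 7157 for the difference between the pairs, 6039 to 9381 for Epcam hi against pB2, and 1341 to 2021 for genes called the same way in both pairs. Left-out fits tested more genes, 16520 to 17368.

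A minimum fold change of 2 left 3846 genes for 687g against Epcam hi, 2699 for 687g against pB3, 1158 called the same way in both pairs and 868 called opposite ways, by construction fewer. Other tools, scalings, filters and the fit of only the libraries compared stayed within 1.5 times of each count; DESeq2 called 6467, 5299, 5684, 7433 and 3738 genes in the order of the contrasts, and a fit of only the 4 libraries compared called 9354, 4207, 7455 and 4227 without the difference between the pairs. Camera called 8, 9 and 2 lists in pB3 against pB2, in 687g against Epcam hi and for the difference between the pairs. With an estimated correlation it called 0, 0 and 0 (2, 1 and 1 at an unadjusted p under 0.05), fry called 18, 15 and 12, and its mixed test called 18, 17 and 18; fry does not compare a list with other genes. With 1 library left out camera called 8 to 9, 8 to 10 and 2 to 3. In these contrasts fry reversed 2 lists relative to their medians and camera: hypoxia and glycolysis in 687g against Epcam hi (median 0.17) and basal and myoepithelial genes for the difference between the pairs (median -0.62); their medians and means differ in sign. The cause of the other changes was not tested.

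With a replicate block the counts were 6995, 5655, 5914, 8006 and 4020, with 1842 called the same way in both pairs, 1396 opposite ways, and 8, 9 and 2 lists. The replicate numbers do not pair the samples: libraries with the same number deviated together by correlations from -0.0982 to 0.173. Counts are limited by depth for genes near the floor, where a single library moved fitted values.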

Other observations

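The gene list tests between lines of different mouse models, the windows in those comparisons, the stretches of chromosomes named and the level of Xist were chosen after results had been seen; libraries were not left out for these lists. Epcam hi had more of the epithelial adhesion genes than pB2: of 24, 14 were higher, 2 lower and 8 not called, also adjusted over the list alone (median 1.03; camera, adjusted p = 0.00864; adjusted p = 0.492 with an estimated correlation). Cdh1 was higher by 1.65 ± 0.22 and Epcam by 1.38 ± 0.17. Hypoxia and glycolysis genes were higher too, with 12 of 17 higher, 1 lower and 4 not called (median 0.75; camera, adjusted p = 0.0435; adjusted p = 0.492 with an estimated correlation). Interferon-stimulated genes were lower in Epcam hi, with 13 of 22 lower, 1 higher and 8 not called (14 lower when adjusted over the list alone; median -1.51; adjusted p = 0.00229; adjusted p = 0.492 with an estimated correlation), as were cell cycle genes, with 13 of 23 lower, 0 higher and 10 not called (median -0.55; adjusted p = 0.0288; adjusted p = 0.492 with an estimated correlation). The Epcam hi libraries themselves differed on the interferon-stimulated genes, with a median of -0.46 in replicate 2 against replicate 1, and less so on the hypoxia (0.25) and cell cycle genes (0.13), so the sizes of these changes depend on the replicate. The other 16 lists had camera adjusted p of 0.0573 or more, and with an estimated correlation camera called 0 lists at any p under 0.05, while fry called 16. Basal and myoepithelial genes had a median of 1.38 and pointed up with camera (adjusted p = 0.78), but down with fry (adjusted p = 5.00e-04).

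687g differed from pB3, although both were rich in Vim. Epithelial adhesion genes were lower in 687g, with 20 of 24 lower, 1 higher and 3 not called (median -5.13; camera, adjusted p = 1.33e-14; adjusted p = 0.114 with an estimated correlation). Cdh1 went from 51.4 to 1.32 CPM and Epcam from 271 to 3.77. Cell cycle genes were lower, with 15 of 23 lower, 0 higher and 8 not called (17 lower when adjusted over the list alone; median -0.70; adjusted p = 4.60e-05; 0.236 with an estimated correlation). MHC class I genes were lower, with 7 of 18 lower, 0 higher and 11 not called (8 lower when adjusted over the list alone; median -0.67; adjusted p = 0.00521; 0.558 with an estimated correlation), and 3 of 17 cholesterol synthesis genes were lower, 0 higher and 14 not called (adjusted p = 0.036; 0.558). TGF-beta response genes were higher in 687g, with 13 of 17 higher, 1 lower and 3 not called (median 1.13; adjusted p = 4.57e-05; 0.503 with an estimated correlation). The adipocyte markers Fabp4 and Plin4 were higher as well (adjusted p = 0.00521; 0.302 with an estimated correlation). The other 14 lists had camera adjusted p of 0.262 or more; with an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05), and fry called 9.

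Genes that neighbour each other on a chromosome differed together between lines. Among overlapping windows of 100 neighbouring expressed genes, 9 of 128 had a median log2 fold change of at least 0.4 in size in pB3 against pB2, and 6 of 130 in 687g against Epcam hi. In 100 shuffles of gene order the highest number was 0 in each comparison. Epcam hi against pB2 gave 12 of 128 windows and 687g against pB3 gave 2 of 136. Broad gene dosage differences, such as copy number changes of parts of chromosomes, may be a cause, as a hypothesis. DNA copy number was not measured here, and co-regulated neighbours are not excluded.

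Some stretches told the lines apart, in both directions. On chromosome 4 from 132530555 to 149496668 genes were higher in pB3 than in pB2 by a median of 0.69. In Epcam hi against pB2 the median was 0.61 from 132348014 to 148627019, and 1.02 in the overlapping window from 136284683 to 156247616. On chromosome 19 overlapping windows had medians of 0.42 to 0.55 in pB3 against pB2, and on chromosome 6 overlapping windows had medians of 0.46 to 0.54 in Epcam hi against pB2 and of -0.51 and -0.42 in 687g against Epcam hi. On chromosome 5 from 3341485 to 54121057 (GRCm38), genes had a median of -1.43 in pB3 against pB2, with 89.3% of 150 lower, and of -1.47 in Epcam hi against pB2. From 134619721 to 145201868 on the same chromosome the medians were -1.25 and -1.31, and on chromosome 11 from 106256154 to 120617936 they were -0.94 and -0.84. In these stretches of chromosomes 5 and 11 the medians lay between -0.017 and 0.085 in 687g against Epcam hi. They lay between -0.0069 and 0.055 in 687g against pB3, so pB2 stood above the other lines there. On chromosome 14 from 7817957 to 55722263 the median was 0.60 in 687g against Epcam hi and -0.46 in Epcam hi against pB2. On chromosome X from 74013914 to 150459154 it was 0.77 in 687g against Epcam hi and 0.70 in 687g against pB3. Xist, the RNA that silences an X chromosome, stood at 34.8 and 56.3 CPM in the 687g libraries, against 388 and 958 in Epcam hi and 707 and 609 in pB3 (edgeR, log2 fold change -3.89 ± 0.47 and -3.85 ± 0.47, adjusted p = 1.61e-05 and 3.03e-05).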
